A study of Homo sapiens with 6 samples.

How the data were processed

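Total RNA from HepG2 cells carrying a lentiviral hairpin against CHROME (shCHROME, 3 libraries) or a non-targeting hairpin (EV, 3 libraries) was made into libraries with an Illumina TruSeq RNA kit and sequenced in pairs on a HiSeq, per the labels' protocols. The packaging cells for the virus were HEK293T, an embryonic kidney line. Groups and replicate letters were taken from the sample titles. Reads were processed with STAR 2.5, featureCounts 1.5.2 and DESeq2 (given as version 3.4) on the genome build hg19, per the submitters' processing notes. Whether the counting used strand, and which annotation it used, is not given in the sources used here, so overlapping, antisense and paralogous genes may share or lose reads.

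The authors deposited 1 table with a normalized value per gene and library, a never-negative signal of read counts divided by a size factor. The same deposited table holds the authors' mean, log2 fold change, p-value and adjusted p-value for each gene. The table had 24656 rows and 23368 distinct genes; 1288 repeated rows were removed, and 28 symbols stored as dates were restored from their Ensembl identifiers. It lists no mitochondrially encoded gene, so that list had no test. The authors' mean differed by over 1% from the mean of the 6 libraries in 7907 of 11274 genes with a mean of at least 100, so it was not taken over these 6 libraries alone; any others are not analysed here. Some genes that liver cells commonly express, such as IRS2 and APOC2, are listed at 0 in each library, so a low value in this table is no evidence that a gene is silent.

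In each library the values were whole multiples of the value of 1 read, within 0.01 reads for 100% of genes, and whole reads were recovered from that step. The step was 0.995698 in EV replicate c, too close to 1 to be accepted by an automatic test for recovered reads, and 0.914083 to 1.114941 in the other libraries. Replicates of a group differed by more than sampling noise, with chi-square per degree of freedom between 5.69 and 17.01.

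The design had assumed raw counts and an edgeR quasi-likelihood test. Since the table holds normalized values, the main test was its stated replacement, limma 3.58.1 with an intensity trend on log2(value + 1), with group as the only term, all 6 libraries, genes kept by filterByExpr of edgeR 4.0.16 on the recovered reads, and Benjamini-Hochberg adjustment. Fold changes are on the log2(value + 1) scale, which understates changes of low genes, and folds in the text are powers of that value. The count tests, edgeR quasi-likelihood and DESeq2 1.42.0, ran on the recovered reads as alternatives. The design foresaw a count test on recovered reads, and the edgeR test was listed as an alternative after seeing the data. They called 1553 and 1608 genes, against 1535 with limma, of which 1508 and 1465 were shared.

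Before the data were examined, 26 gene lists were fixed, and 25 with at least 5 measured genes were tested with camera (preset correlation 0.01), adjusted over the lists. The design named log2 CPM with a prior count of 2 for this step; the log2(value + 1) values were used in its place, and the version of the design gave the same counts of 10 lower and 2 higher lists. Camera with an estimated correlation and fry were alternatives. Named genes followed a rule fixed at the same time: 10 genes of the literature on CHROME; the 10 largest changes in each direction among genes with adjusted p under 0.05, a mean count of at least 50 and no overlap of the groups in CPM; the 5 most expressed called genes per direction; and up to 4 members of each list, called ones first and otherwise the most expressed. CHROME was to be named first, but is not analysed here, and some genes that the rule names are not reported here.

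Alternatives covered library scaling (DESeq2 size factors, upper quartile, library totals, and TMM, the last, named in the design for the edgeR test, listed as an alternative after seeing the data), filters (none beyond 1 read, or 1 CPM in at least 3 libraries), a pseudocount of 0.1, a replicate block and leaving out each library. The limma step was tested on simulated data, in which 200 of the genes had known changes. It recovered 28.6% of genes changed 1.2-fold, 82% at 1.5-fold, 89.8% at 2-fold and 100% at 4-fold, and 16 of its 165 calls (9.7%) were genes without a change, above the nominal 5%.

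For microRNA sites, the longest annotated 3' untranslated region per gene was taken from GENCODE release 29 by gene identifier, without use of coordinates; 12413 of 14598 tested genes (85%) had one. The planned comparison was of mean log2 fold changes after regression on log2 length. In simulated data with a shift of -0.05, regressing the fold changes alone gave -0.0363, because sites are commoner in long regions. Fitting site and length together gave -0.05. Both values are the fit with the shift minus the fit of the same data without it. For the joint fit this difference equals the shift by construction, so it is no independent test of that fit. The joint fit was used, a change made before any real value of this test was seen. R 4.3.3, Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9 were used.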

Results

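Messenger RNA was measured in HepG2, an established human liver cancer line that keeps many hepatocyte functions, after delivery of a short hairpin RNA by lentivirus. The hairpin in 3 libraries (shCHROME, replicates a, b and c) was directed at CHROME, a long noncoding RNA. The hairpin in the other 3 libraries (EV, replicates a, b and c) was a non-targeting control. Recovered read totals ran from 29188213 in EV replicate a to 35429420 in EV replicate b, and from 29477352 to 33911426 in the shCHROME libraries. The most abundant gene, EEF1A1, took between 2.64% and 2.96% of the reads of a library. The first principal component of the log2 values carried 39.1% of their variance and separated the groups, with EV libraries between -18.3 and -17.2 and shCHROME libraries between 16.7 and 18.7. No source states that the libraries came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

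The comparison addresses which transcripts change when CHROME, a regulator of cholesterol homeostasis in the literature, is knocked down. CHROME itself was not analysed here, so the extent of the knockdown has no measurement beside the results that follow.

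EDNRB, an endothelin receptor, rose in shCHROME cells from 4.521 ± 3.28 to 110.7 ± 17.2 normalized counts (SD, n = 3 per group). SLCO1B3, a hepatic uptake transporter of organic anions, rose 11.8-fold, from 19.83 ± 2.16 to 243.6 ± 3.83 normalized counts. SEMA3A, a secreted axon guidance factor, rose 3.86-fold, DKK1, a secreted Wnt inhibitor, 3.03-fold, and the growth factor FGF2 2.77-fold. SETBP1 rose 3.39-fold, the adhesion receptor LPHN2 2.62-fold, the sulfotransferase CHST15 2.54-fold and C16orf45 2.43-fold. MTRNR2L10 rose 2.38-fold, with an SD of 193 around a mean of 336.6 normalized counts in shCHROME. It is a nuclear copy of mitochondrial ribosomal RNA, as is MTRNR2L2, which rose 1.34-fold, and reads shared between such copies leave both values uncertain.

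KNG1, which encodes kininogen, fell from 345.6 ± 21 to 108.4 ± 16.3 normalized counts (SD, n = 3 per group), a 3.19-fold decrease. PLG, which encodes plasminogen, fell 2.88-fold. DIO1, a thyroid hormone deiodinase, fell 2.78-fold. The potassium channel gene KCNK3 fell 4.42-fold and the inhibitor of apoptosis gene BIRC7 3.14-fold. C10orf54 fell 5.05-fold, C3orf25 3.93-fold and the protocadherin gene PCDH1 2.71-fold. The 20 largest changes under the naming rule, 10 per direction, had limma adjusted p between 2.16e-09 for SLCO1B3 and 0.0056 for C16orf45.

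**Figure D1:**
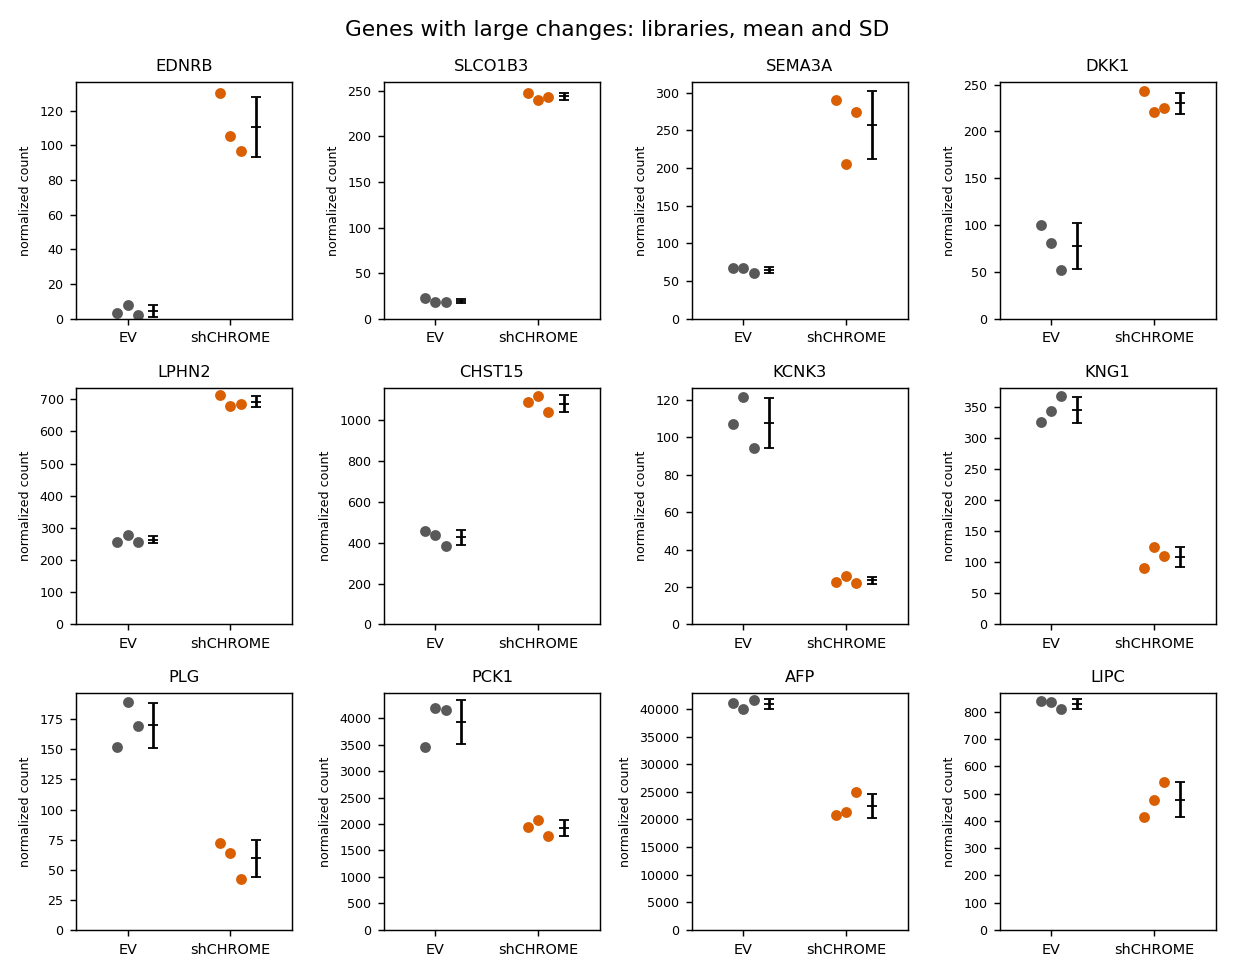
Normalized counts of 12 genes in each library (points), with the mean and SD of each group (bars), in EV and shCHROME cells; the vertical axes are linear and start at 0. In each panel the 3 shCHROME libraries lie on one side of the 3 EV libraries, above them for EDNRB, SLCO1B3, SEMA3A, DKK1, LPHN2 and CHST15 and below them for the other genes.

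Among the most abundant transcripts that changed, ALB, which encodes albumin, fell 1.25-fold, from 722800 ± 28400 to 580000 ± 54500 normalized counts (SD, n = 3 per group). A2M, a plasma protease inhibitor, fell 1.43-fold, APOA1, the main protein of high-density lipoprotein, 1.29-fold, fibronectin (FN1) 1.17-fold and ITIH2 1.15-fold. In the other direction, the small nucleolar RNA SNORD17 rose 1.25-fold, the axon guidance receptor gene ROBO1 1.2-fold, HSP90AA1 1.17-fold and MDM2 1.16-fold. Over 16 alternatives, FN1 and ITIH2 lost the call in 8 each, ALB and HSP90AA1 in 4 each and MDM2 in 3, most of them with 1 library left out, and adjusted p reached 0.171 for FN1 and 0.141 for ALB.

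Over all 14598 genes tested with limma, 532 were higher and 1003 lower in shCHROME at an adjusted p under 0.05. Of these, 47 were at least 2-fold higher and 73 at least 2-fold lower. Changes were mostly small: 78.1% of the called genes moved by less than 1.5-fold, and their median absolute log2 fold change was 0.36. The groups did not overlap in 4092 genes, or 28%, in normalized values and in 4459 genes, or 30.5%, in CPM, where chance gives 10%. The balance of directions depended on the scaling of the libraries. Lower genes were 65.3% of the calls with the authors' scaling and 42.9% (936 higher, 702 lower) when libraries were scaled to their totals. Under the other scalings they were between 58.5% and 66%. The number of calls also depended on single libraries: 245 genes were higher and 599 lower without shCHROME replicate c, 297 and 635 without EV replicate a, and 323 and 649 without EV replicate c. In the authors' deposited table, 446 genes were higher and 888 lower at the same threshold. Of these 1334 genes, 1306 were also called here, all in the same direction. By the authors' own fold changes, 5 and 4 were at least 2-fold higher and lower. Those fold changes are another measure than the limma ones used here, so these counts are not comparable with 47 and 73.

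**Figure D2:**
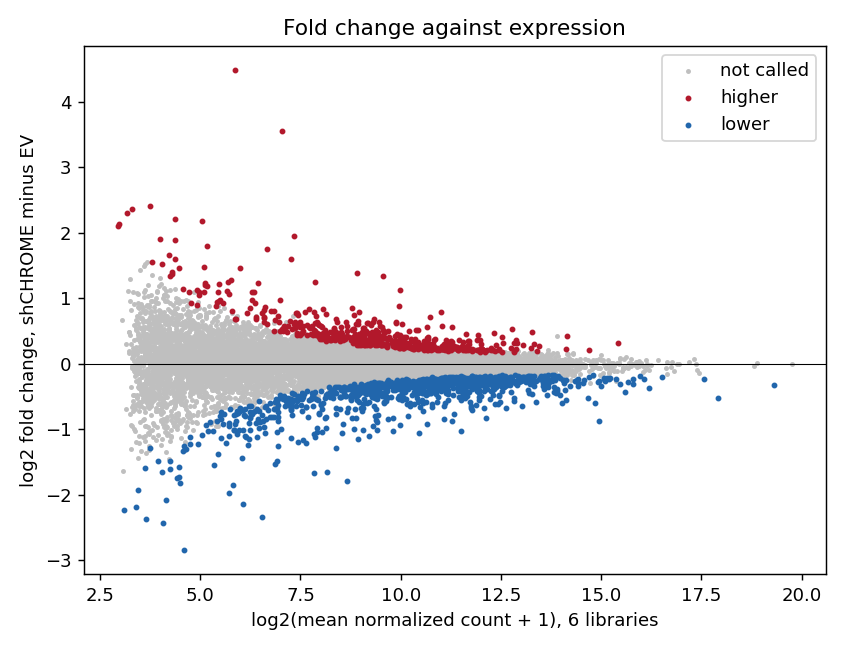
Log2 fold change (shCHROME minus EV) of each of the 14598 tested genes against log2 of its mean normalized count plus 1 over the 6 libraries; red and blue points are the 532 higher and 1003 lower genes, grey points the rest. Called genes appear over the whole range of expression, and changes beyond 1 on the log2 scale are fewer among highly expressed genes.

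Genes of cholesterol efflux and transport were lower as a group. Of 22 measured members, 9 fell, none rose and 13 did not pass the test, and 9 were lower adjusted over the list alone. ABCA1, the transporter that loads cholesterol onto apolipoprotein A-I, fell 1.18-fold, from 6223 ± 253 to 5255 ± 288 normalized counts (SD, n = 3 per group, limma adjusted p = 0.0119). LIPA, the lysosomal acid lipase, fell 1.41-fold, and ABCG8, which exports sterols into bile, 1.33-fold. STARD5, a sterol-binding protein gene, fell 1.65-fold, a call that was lost in 9 of 16 alternatives, DESeq2 among them (adjusted p = 0.0515, and up to 0.191 over all alternatives). NPC1, which moves cholesterol out of lysosomes, was 1.13-fold lower with a limma adjusted p of 0.0488, and its call was lost when libraries were scaled to their totals (adjusted p = 0.136) and when any 1 library was left out (0.0263 to 0.206 over all alternatives). The call of ABCA1 was lost without EV replicate c (adjusted p = 0.0602, with 0.00245 as the lowest of its alternatives). Camera gave the group an adjusted p of 1.84e-05 with the preset correlation, and adjusted p = 0.275 with an estimated correlation.

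Several other genes reported as targets of microRNAs that CHROME binds in the literature did not pass the test, nor did PRKRA, the gene beside CHROME. CROT had a log2 fold change of -0.05 (95% interval -0.26 to 0.15), PRKAA1 of -0.04 (-0.17 to 0.09), ATP8B1 of 0.05 (-0.27 to 0.38) and PRKRA of 0.12 (-0.01 to 0.25). OSBPL6 had 19 reads over the EV libraries and 17 over the shCHROME libraries, ABCG1 had 6 and 17, and ABCB11 had 1 and 2, so these genes were below the expression filter. Without the filter none passed the test, with a log2 fold change of 1.16 for ABCG1 (limma adjusted p = 0.171). CPT1A, which admits fatty acids to mitochondria, fell 1.18-fold (adjusted p = 0.0129), a call that was lost without EV replicate a, EV replicate c or shCHROME replicate c (adjusted p = 0.0735, 0.0794 and 0.0597, with 0.00244 as the lowest of its alternatives). Among literature targets of miR-33, 6 of 19 measured genes fell and none rose, PIM1 and HADHB among them, with 6 lower adjusted over the list alone. The call of PIM1 was lost without shCHROME replicate c (adjusted p = 0.0545) and that of HADHB without EV replicate c (0.0618). For this list camera gave an adjusted p of 0.0271, and adjusted p = 0.361 with an estimated correlation. Its call was also lost with library totals (0.0642) and without EV replicate c (0.094), shCHROME replicate a (0.0565) or shCHROME replicate b (0.0715). Among literature targets of miR-27 and miR-128, 5 of 22 fell and none rose, with 6 lower adjusted over the list alone. The nuclear receptor gene RXRA fell 1.34-fold and the insulin receptor gene INSR 1.25-fold. The camera adjusted p was 0.0192, and adjusted p = 0.35 with an estimated correlation, and the call was lost without EV replicate c (0.081) or shCHROME replicate c (0.0666).

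**Figure D3:**
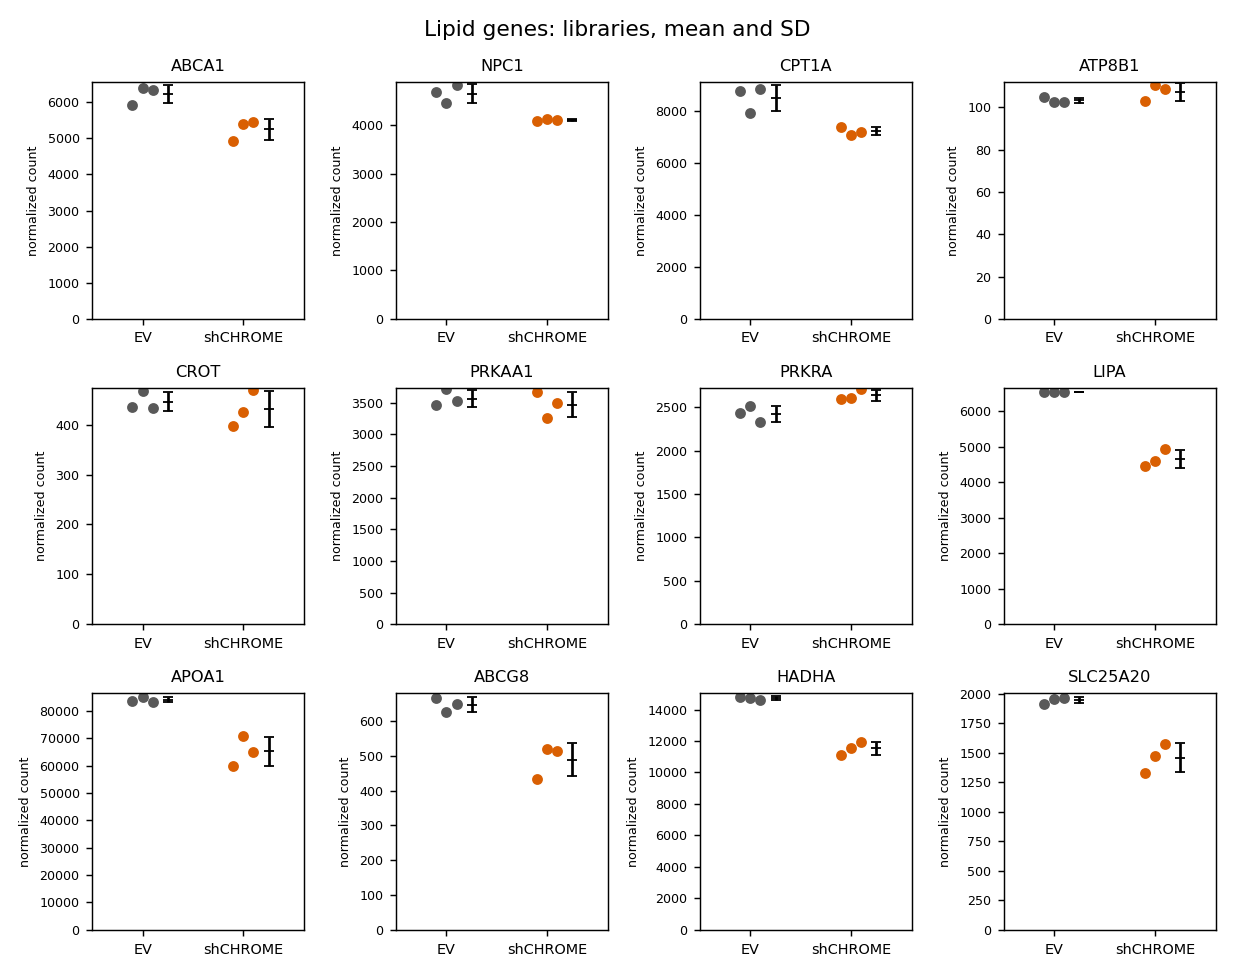
Normalized counts of 12 lipid genes in each library (points), with the mean and SD of each group (bars), in EV and shCHROME cells; the vertical axes are linear and start at 0. The libraries of the 2 groups lie apart for LIPA, APOA1, ABCG8, HADHA and SLC25A20, while ATP8B1, CROT and PRKAA1 show overlapping libraries.

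Fatty acid oxidation had the largest proportion of called members among the 25 tested lists. Of 21 measured members, 11 fell, none rose and 10 did not pass the test, with 11 lower adjusted over the list alone. The lipase inhibitor gene ANGPTL4 fell 1.43-fold, the carnitine carrier gene SLC25A20 1.34-fold, and HADHA, of the mitochondrial trifunctional protein, 1.28-fold. Camera gave the list an adjusted p of 9.94e-07, and adjusted p = 0.275 with an estimated correlation. In fatty acid and triglyceride synthesis, 3 of 19 measured genes fell (LPIN1 1.3-fold, AGPAT2 1.25-fold and FADS1 1.25-fold, the call of AGPAT2 being lost in 3 of 16 alternatives), with 3 lower adjusted over the list alone, and the list was not called (camera adjusted p = 0.238). Sterol synthesis and uptake gave no calls among 24 measured genes, over all genes or adjusted over the list alone (camera adjusted p = 0.9). The log2 fold change was 0.05 for CYP51A1 and 0.04 for SREBF2. Of 11 LXR targets, 3 fell and none rose, with 3 lower adjusted over the list alone, SMPDL3A among them at 1.22-fold, its call lost in 5 of 16 alternatives (camera adjusted p = 0.0192, and adjusted p = 0.35 with an estimated correlation). The call of the LXR list was lost without EV replicate c (0.0573) or shCHROME replicate a (0.109).

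Of 19 measured lipoprotein genes, 7 fell, 1 rose and 11 did not pass the test, with 10 lower and 2 higher adjusted over the list alone. Hepatic lipase (LIPC) fell 1.74-fold and APOA4 1.74-fold, while endothelial lipase (LIPG) rose 1.97-fold, a call lost without shCHROME replicate b (adjusted p = 0.0506). As a list they were lower with a camera adjusted p of 6.37e-05, a call lost with an estimated correlation (adjusted p = 0.35) and with fry (adjusted p = 0.0698). Of 30 hepatocyte identity genes, 10 fell, 3 rose and 17 did not pass the test, with 11 lower and 4 higher adjusted over the list alone. PCK1, the rate-limiting enzyme of gluconeogenesis, fell 2.03-fold, alpha-fetoprotein (AFP) 1.83-fold and transthyretin (TTR) 1.65-fold, whereas the vitamin D binding protein gene GC rose from 6.01 ± 0.833 to 33.52 ± 15.8 normalized counts (SD, n = 3 per group). The camera adjusted p was 0.0192, and adjusted p = 0.35 with an estimated correlation. In bile acid synthesis and transport, 4 of 17 fell and 1 rose, with 6 lower and 2 higher adjusted over the list alone. SLC27A5 fell 1.36-fold, ABCC3 1.34-fold and ABCB4 1.27-fold, and BAAT rose 1.18-fold (camera adjusted p = 0.0118, and adjusted p = 0.35 with an estimated correlation). The call of the bile acid list was lost without shCHROME replicate a (0.0846). The call of BAAT was lost in 6 of 16 alternatives (adjusted p up to 0.217) and that of SLC27A5 without shCHROME replicate c (0.0613).

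Markers of cholangiocytes and liver progenitors were higher as a group. KRT19 rose 1.55-fold, SOX4 1.53-fold and osteopontin (SPP1) 1.4-fold, and the other 4 of 7 measured members did not pass the test; 3 were higher adjusted over the list alone. The camera adjusted p was 0.0109, adjusted p = 0.118 with no expression filter, and adjusted p = 0.275 with an estimated correlation. Cell proliferation genes were higher by a small amount, with a median log2 fold change of 0.11 and 22 of 25 members positive, but only CENPF was called, at 1.19-fold and with its call lost in 5 of 16 alternatives, and none adjusted over the list alone. The camera adjusted p of 0.0118 was lost without shCHROME replicate b (0.154) or c (0.0836), and was 0.775 with an estimated correlation.

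Interferon-stimulated genes and the unfolded protein response were lower as lists. Of 24 interferon-stimulated genes, 5 fell and none rose, with 10 lower adjusted over the list alone. IFIT1 fell 1.84-fold, CMPK2 1.6-fold, IFIT3 1.49-fold and IFI6 1.46-fold (camera adjusted p = 4.09e-05, and adjusted p = 0.185 with an estimated correlation). The call of CMPK2 was lost in 10 of 16 alternatives, DESeq2 among them (adjusted p = 0.0672, and up to 0.221 over all alternatives), and those of IFIT3 and IFI6 in 3 each. Of 19 genes of the unfolded protein response, 6 fell and none rose, with 9 lower adjusted over the list alone. HERPUD1 fell 1.33-fold, MANF 1.28-fold, DNAJB9 1.2-fold and PDIA4 1.19-fold (camera adjusted p = 4.09e-05, and adjusted p = 0.35 with an estimated correlation). In the integrated stress response, 4 of 19 rose, VLDLR 1.51-fold, SESN2 1.25-fold, SLC7A11 1.15-fold and ASNS 1.14-fold, with 4 higher adjusted over the list alone, and the list was not called (camera adjusted p = 0.198). In these lists the calls of DNAJB9, SLC7A11 and ASNS were lost in 6 of 16 alternatives each, of VLDLR in 3 and of PDIA4 in 2.

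**Figure D4:**
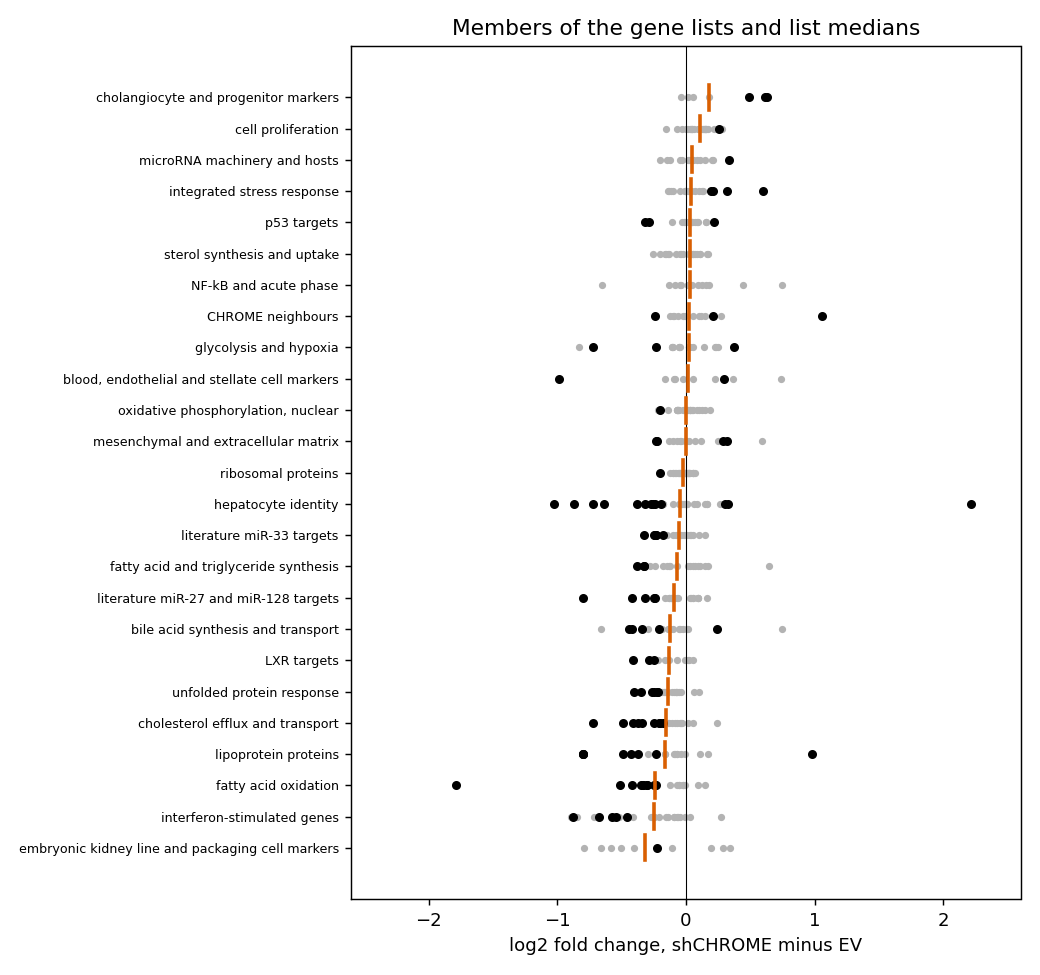
Log2 fold change (shCHROME minus EV) of each measured member of the 25 tested gene lists; black points are members called with limma, grey points members that were not, and orange bars list medians. The medians run from -0.32 for embryonic kidney and packaging cell markers to 0.18 for cholangiocyte and progenitor markers.

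In total 10 of the 25 tested lists were lower and 2 higher with camera at the preset correlation. With an estimated correlation none was called. The lists share called members, so their calls are not independent results. ABCA1 is in the cholesterol, miR-33, miR-27 and miR-128, and LXR lists. Of the falling miR-33 targets, NPC1 is also in the cholesterol list, and CPT1A and HADHB in that of fatty acid oxidation. ABCG8 is in the cholesterol and LXR lists, and ABCB4 in the cholesterol and bile acid lists. The remaining lists of the 25 had no call with camera. Among p53 targets, MDM2 rose while CDKN1A fell 1.25-fold and CCNG1 1.22-fold (camera adjusted p = 0.707). In glycolysis and hypoxia, NDRG1 fell 1.65-fold and ALDOA 1.18-fold and HK2 rose 1.29-fold (0.829). In oxidative phosphorylation 1 of 24 genes fell, UQCRC2 at 1.15-fold (0.924), and in ribosomal proteins 1 of 28, RPS9 at 1.15-fold (0.501). No gene of the NF-kB and acute phase list was called among 15 (0.728). In the mesenchymal list LOX rose 1.22-fold while FN1 and CDH2 fell (0.9). Among neighbours of CHROME, DFNB59 rose 2.08-fold, HNRNPA3 rose 1.16-fold and NFE2L2 fell 1.18-fold (0.584). In microRNA machinery and hosts R3HDM1 rose 1.26-fold (0.308). Among blood, endothelial and stellate cell markers PDGFRB fell 1.98-fold and LYZ rose 1.22-fold (0.9). Markers of embryonic kidney and packaging cells had a median log2 fold change of -0.32 over 10 measured genes, of which CDH2 alone was called (0.13, and adjusted p = 0.0139 with fry). In these lists, calls were lost in 7 of 16 alternatives for UQCRC2, in 6 for RPS9 and HNRNPA3, in 5 for R3HDM1, in 4 for LOX and NFE2L2, in 3 for CDH2, DFNB59 and LYZ, and in 2 for ALDOA. In these uncalled lists, counts adjusted over the list alone differed from those over all genes only in glycolysis and hypoxia (2 higher), the mesenchymal list (3 higher), microRNA machinery and hosts (2 higher) and ribosomal proteins (0 lower).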

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

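The tests of scaling on the balance of directions, of packaging cell markers, of other splits, and of scaling, GC content and transcript length over all measured lipid genes were chosen after the results they concern were seen. Of 3587 genes listed at 0 in each of the 6 libraries, 419 had an authors' deposited mean above 0. For these genes that mean took in signal outside the compared values. In 2 of them it was above 0.5, the level that 3 reads over 6 libraries allow, and reached 0.595.

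More genes were lower than higher in shCHROME, 1003 against 532. The scaling of the libraries may account for this balance. The share of calls that were lower was 65.3% with the authors' scaling, 65.1% with DESeq2 size factors and 66% with TMM. It was 58.5% with upper quartile scaling and 42.9% with library totals, the lowest of the 5 scalings. Library totals alone gave fewer lower than higher genes. The median log2 fold change of all genes moved from 0.01 to 0.06 between the authors' scaling and library totals. Of the 10 splits of the 6 libraries into 3 and 3, only 1, the real one, gave as many calls (1535), and the highest other split gave 1; with 10 splits the share cannot go under 0.1, so the splits are too few to judge chance. An effect of the hairpin on the balance remains open as well.

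The lists of fatty acid oxidation, lipoproteins and cholesterol transport had median log2 fold changes of -0.24, -0.16 and -0.15 over all their measured members. They were lower with camera at the preset correlation, but not with an estimated correlation (adjusted p = 0.275, 0.35 and 0.275). Over all 59 measured members the median was -0.16. Removing a smooth trend on GC content and transcript length left it at -0.15 (95% bootstrap interval over genes -0.26 to -0.09), which argues against such a trend as the whole cause. That reading rests on a bound changed after the values were seen: the median below -0.1 with an interval clear of values within 0.05 of 0. The bound tried first, the whole interval below -0.1, was not met and would leave the trend open. The median of the 59 members minus that of all genes was -0.17 under each of the 5 scalings. Its 95% bootstrap interval over genes was -0.25 to -0.09. Scaling moves all genes alike, so this agreement between scalings was fixed in advance. These lists were also taken up after camera had called them lower than other genes. The gap therefore restates that result, and no conclusion on scaling is drawn from it. Both intervals treat genes as independent. The 26 members called lower had a median of -0.35. Carried-over packaging cells, as the source of the whole fall, would raise their markers; the median log2 fold change of the 10 measured markers was -0.32, and these are also expressed in the control cells. A response to the hairpin, through CHROME or not, stays open as a hypothesis, and since the shCHROME titles all carry the same hairpin name, an effect of its sequence was not separated from an effect of CHROME.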

How the results depend on the processing

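The design had named the edgeR test, TMM and camera on log2 CPM as its own choices for raw counts, and the edgeR test, TMM scaling of the limma fit and camera on log2 CPM were listed as alternatives after seeing the data. Higher genes numbered 936 with library totals and 349 with the replicate block, against 532. Leaving out 1 library gave 245 to 528 higher and 599 to 1051 lower genes, 31 to 49 at least 2-fold higher, 1 to 2 lists higher and 7 to 10 lists lower. Over 17 alternatives per list, the call was lost in 6 for miR-33 targets, in 4 each for miR-27 and miR-128 targets, for LXR targets and for cell proliferation, in 3 for bile acids, and in 2 each for lipoproteins, hepatocyte identity and cholangiocyte markers. Genes at least 2-fold higher were 29 with 1 CPM in at least 3 libraries, which tests fewer genes. Lists higher were 1 without a filter, 0 with an estimated correlation and 1 with fry; lists lower were 0 with an estimated correlation and 5 with fry. Those 5 are 4 of the 10 found with camera (cholesterol efflux and transport and fatty acid oxidation, 0.0188 each, interferon-stimulated genes, 0.0139, and the unfolded protein response, 0.0471) and 1 that camera did not call, embryonic kidney and packaging cell markers (0.0139). The lipoprotein list was lost with fry (adjusted p = 0.0698). Where not stated, the cause was not tested. Among named genes, 1492 values under alternatives kept their direction and side of the threshold, 160 lost the call, 1 gained it and 10 changed sign; for lists the numbers were 373, 31, 1 and 20. No result that changed sign was called in either setting. With library totals PRKAA1 went to a log2 fold change of 0.01 and ORM2 to 0.012. Leaving out 1 library gave log2 fold changes of -0.115 to 0.006 for CROT, -0.08 to 0.005 for PRKAA1, -0.001 to 0.126 for CYP51A1, -0.068 to 0.171 for SREBF2, -0.044 to 0.053 for ORM1 and -0.124 to 0.13 for CCL20. Lists changed direction with library totals (camera adjusted p = 0.949 for sterol synthesis and uptake and for blood, endothelial and stellate cell markers, 0.685 for oxidative phosphorylation and 0.958 for ribosomal proteins), upper quartile scaling (0.938 for oxidative phosphorylation), 1 CPM in at least 3 libraries (0.936 for blood, endothelial and stellate cell markers) and fry (0.699 for the mesenchymal list). Direction also changed with 1 library left out. Where it changed, adjusted p was 0.0585 to 0.848 for sterol synthesis and uptake and 0.999 for fatty acid and triglyceride synthesis. It was 0.711 for p53 targets, 0.435 and 0.687 for oxidative phosphorylation, and 0.659 and 0.908 for NF-kB and acute phase. It was 0.776 and 0.852 for blood, endothelial and stellate cell markers and 0.846 and 0.965 for ribosomal proteins. The next ranges cover all fits with 1 library left out, including those that kept direction. They were 0.0584 to 0.999 for fatty acid and triglyceride synthesis, 0.357 to 0.776 for p53 targets and 0.435 to 0.954 for oxidative phosphorylation. For NF-kB and acute phase the range was 0.284 to 0.908, and for ribosomal proteins 0.0846 to 0.965. For blood, endothelial and stellate cell markers it was 0.709 to 0.9. The letters are not stated to pair the libraries, and the values showed no sign of pairing. Same-letter deviations correlated at -0.05, -0.09 and 0.04, and not every library correlated best with its own letter. These values cannot settle whether libraries of the same letter were prepared together. The replicate block gave 1113 calls against 1535.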

Other observations

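The lists in the first 2 paragraphs were written after the main results were seen, and contain some genes that led to them. The cytochrome P450 family was lower: of 34 measured genes 11 fell, 2 rose and 21 did not pass the test. CYP2J2, which makes epoxides of arachidonic acid, fell 2.05-fold, CYP4F11 1.76-fold, CYP24A1, which inactivates vitamin D, 1.5-fold and CYP2W1 1.24-fold, while CYP19A1, the aromatase gene, rose 1.68-fold. Members of the CYP4F cluster are similar in sequence, and reads shared between them leave their values uncertain. The camera adjusted p was 0.00123, and adjusted p = 0.264 with an estimated correlation.

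In coagulation and fibrinolysis 5 of 24 measured genes fell and 2 rose. Besides KNG1 and PLG, F10 fell 1.43-fold, SERPIND1 1.28-fold and PROS1 1.17-fold, and F13B rose 2.29-fold (camera adjusted p = 0.00398, and adjusted p = 0.264 with an estimated correlation). In complement 6 of 19 fell and 1 rose: C4BPA fell 1.51-fold, C1S 1.32-fold and C2 1.23-fold, and C8A rose 1.34-fold (0.0407, and adjusted p = 0.264 with an estimated correlation). Conjugation and detoxification genes were not called as a list (0.0948), although EPHX1 fell 1.45-fold and SULT2A1 1.39-fold. Axon guidance genes went both ways, with UNC5B up 1.63-fold and PLXNA2 down 1.6-fold (0.614), as did amino acid and urea metabolism, with ASS1 down 1.53-fold and CPS1 up 1.24-fold (0.361). Of 28 measured Wnt pathway genes, 24 did not pass the test, 3 fell and 1, DKK1, rose (0.5). Among those that fell, AXIN2 fell 1.2-fold and TBX3 1.21-fold. As a check on the choice of lists, genes named before and all genes of the fixed lists were taken out, which left 28 cytochrome P450 genes, 18 of coagulation and all 19 of complement. These 3 lists remained lower with camera at the preset correlation (adjusted p = 0.0231, 0.0143 and 0.0407). The reduced cytochrome P450 and coagulation lists were not tested with an estimated correlation. For complement nothing was taken out, so the check adds nothing there. A hypothesis is that liver functions beyond lipid metabolism may also be lower, but no full list was called with an estimated correlation.

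A planned test asked whether release of miR-33, miR-27 and miR-128 may lower genes with their sites. Genes with a 7-mer or 8-mer site (6313) had a mean log2 fold change 0.0076 higher than genes with none (6097), with a 95% interval of -0.004 to 0.0193 and a permutation p of 0.2 (2-sided, 100000 resamples). The difference was 0.0012 with 8-mer sites only (permutation p = 0.877) and 0.0075 with DESeq2 fold changes (permutation p = 0.21). The interval comes from permuting genes, so it treats them as independent and leaves out the spread between libraries. A mean decrease beyond 0.004 on the log2 scale lies outside it, but is not excluded for that reason. A smaller decrease, or one limited to a few genes, stays open. Split by family after the result for all sites was seen, the difference was 0.016 for miR-33, opposite to the predicted direction. Its permutation p was 0.0147, and 0.0441 adjusted over the 3 families. The difference was 0.0073 for miR-27 and -0.0003 for miR-128. These fits removed length but not GC content, and their p-values treat genes as independent, so the miR-33 difference is not read as an effect.

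An off-target effect of a hairpin through its own seed could lower genes that share a heptamer in their 3' untranslated regions. Over 16316 heptamers and 12410 genes, the lowest z, after regression on length and GC content, was -4.28, and 18 of 100 permutations of the genes gave a z as low. The bound set beforehand, the lowest z of the permutations (-4.91), was not passed. That bound was too weak to exclude the explanation, since a seed effect smaller than the range of the permutations would not be seen and the hairpin sequences were not used here.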
